A study of Mus musculus with 4 samples.

How the data were processed

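RNA sequencing measured gene expression in sorted striatal neurons of male mice on the FVB/NJ background, aged 5 to 6 months. BACHD mice carry a bacterial artificial chromosome (BAC) with the full-length human huntingtin gene and 97 glutamines, and their wild-type (WT) littermates do not. Either line was crossed to a reporter line in which EGFP marks neurons with dopamine receptor D1 (D1 cells, direct-pathway medium spiny neurons) or dopamine receptor D2 (D2 cells, indirect-pathway medium spiny neurons). Cells were isolated by fluorescence-activated sorting for GFP, and each library was made from cells pooled from 4 animals, with 150000 cells per animal, per the series' design text. There were 4 groups with 1 library each (D1 WT, D1 BACHD, D2 WT and D2 BACHD), so D1 and D2 cells also differ in reporter line.

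The deposited estimated counts, 1 value per gene and library, were not all whole numbers (19.4% of entries were not whole). The authors also deposited FPKM values, which are scaled by gene length and library size, for the same 37620 Ensembl gene identifiers. Sequencing gave paired 50-base reads, per the series' design text, and CASAVA 1.8.2 was used, per the submitters' processing notes. The aligner, the counting tool, its use of strand, the annotation and the genome build are not given in the sources used here. Reads shared between paralogs, pseudogenes or overlapping genes, and reads from antisense partners, are therefore of uncertain assignment.

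Estimated counts were rounded to whole numbers. Gene symbols were matched by identifier, without the version, for 32897 identifiers. The other 4723 carried 1.52% of counts, and 502 of them were among the genes tested. Genes with at least 1 CPM (counts scaled to the library total) in 2 or more of the 4 libraries were kept, which left 13400. Library scaling was by TMM. Coordinates come from GENCODE M21 on GRCm38, which need not be the build the authors used.

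With 1 library per group, BACHD and WT were compared within a cell type by a rule of size and no test. A gene passed at a ratio of 2 or more either way when the exact conditional binomial 95% interval of the ratio excluded 1. Counts under 3 were set to 3 for the ratio. These intervals cover counting error only, since PCR copies are not independent molecules and variation between pools is not included. The number of genes passing the same way in both cell types was set beside the number of independent lists, which is the product of the list sizes divided by the genes tested.

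Effects common to both cell types were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 4 libraries with terms for cell type and genotype. This fit leaves 1 residual degree of freedom, and its residual is the difference of the genotype effect between the cell types. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE is the absolute log2 fold change divided by the square root of the F statistic. The p-values and SEs rest on that residual and, to a larger part, on variance shared across genes (median of 6.67 prior degrees of freedom). No group had a replicate pool, so the spread between pools of a group was not measured.

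Before the data were examined, 37 gene lists were fixed (pathways, neuronal genes and markers of other cell types). For each of the 31 lists with 5 or more measured genes, the median log2 ratio per cell type was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The genotype term was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists. The preset test sets a list against the spread between genes, not between pools. The estimated correlation rests on 1 residual degree of freedom, so a list could hardly pass by it. Named genes follow a rule also fixed then. It takes Htt, then the 10 genes with the largest ratio each way per cell type among those past the size rule with at least 10 CPM in a compared library. It adds the 10 largest fitted changes each way per model term among called genes with a mean of at least 10 CPM, up to 4 members per list with at least 5 CPM, any D1, D2 or shared medium spiny neuron list member, and the 10 genes whose ratios differ most between cell types. Other genes named were chosen after their values were seen. Values of some genes taken by the rule are not reported here.

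Alternatives were total-count scaling, DESeq2 1.42.0 size factors and its Wald test, no expression filter, a filter of 10 CPM, a ratio of 1.5, FPKM with pseudocounts of 0.1 and 1, limma-trend on log2 FPKM, a model with only the term tested, an adjusted p under 0.1 and leaving out each library in turn, for which only the term tested was fitted, since 3 libraries leave no residual degree of freedom with both terms. The steps were tested on simulated data for the 13400 genes. Counts were drawn at the dispersion trend of the fit, with no variance particular to a gene. Each change was the same in both cell types, with no difference of genotype effect between them. The recovery and false calls may therefore look better than in the real data. The additive genotype test recovered 58% of genes changed 1.3-fold, 84% at 1.5-fold, 94% at 2-fold and 100% at 4-fold (50 genes each), with 12 false calls. At a true ratio of exactly 2, the size rule recovered 46% in D1 and 50% in D2 cells, and at 4 it recovered 100% in each, with 26 false calls in D1 and 16 in D2 cells. Figures were drawn with Python and matplotlib.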

Results

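The series compared D1 and D2 medium spiny neurons of BACHD mice with those of WT littermates, to ask how full-length mutant huntingtin alters expression in each striatal output pathway. The 4 pooled libraries held 41684397 (D1 WT), 41325647 (D1 BACHD), 44523622 (D2 WT) and 43857032 (D2 BACHD) estimated counts. A count of 3 corresponded to 0.0720, 0.0726, 0.0674 and 0.0684 CPM in the same order. Mitochondrially encoded genes took 5.87%, 8.03%, 8.37% and 9.34% of counts. Each group was 1 pool, so no value below has a replicate within its group.

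Mouse Htt stood at 159.1 CPM in D1 WT, 159.2 in D1 BACHD, 159.7 in D2 WT and 148.8 in D2 BACHD. Its genotype change was -0.05 ± 0.05 (log2, SE; edgeR adjusted p = 0.709). The transgene is human, so these mouse counts do not check the genotype labels.

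The first comparison asked whether the sorts separated the pathways. Drd2 stood at 2098 and 2036 CPM in the D2 libraries and at 20.2 and 20.4 in the D1 libraries (WT, then BACHD). Adora2a, the adenosine receptor of indirect-pathway neurons, was higher in D2 cells by 6.35 ± 0.08 (log2, SE; edgeR adjusted p = 7.26e-09). Penk, which encodes proenkephalin, was higher by 6.16 ± 0.08. Drd1 was higher in D1 cells, with a D2 minus D1 log2 difference of -5.78 ± 0.09 (adjusted p = 1.34e-08), and so were Pdyn, which encodes prodynorphin (-8.78 ± 0.15), and the transcription factor gene Isl1 (-8.54 ± 0.16). All 11 measured direct-pathway markers were called higher in D1 cells, and 9 of 10 indirect-pathway markers were called higher in D2 cells. The exception was Gprin3 (0.04 ± 0.11, adjusted p = 0.861). In all, 913 genes were called higher in D2 and 1361 in D1 cells (n = 2 pools of each, edgeR adjusted p under 0.05). This term is also the difference between the reporter lines. Sfxn1, a direct-pathway marker called higher in D1 cells (D2 minus D1 log2 difference -4.41), lies within 250 kb of Drd1. Ttc12 (8.16 ± 0.17) and Ankk1 (7.35 ± 0.16), called higher in D2 cells, lie on chromosome 9 beside Drd2 (49340627 to 49408177), at 49436963 to 49486225 and 49415194 to 49427021 (GRCm38). With total counts as the scale the split was 735 higher in D2 and 2207 in D1 cells, and with limma-trend on FPKM plus 0.1 it was 536 and 1410. DESeq2 called 1330 genes and edgeR 810 without the filter and 1449 with cell type as the only term, a fit that gave 821 without D2 WT and 887 without D2 BACHD.

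The next comparison asked which genes differed by genotype in both cell types. Igfbp4, which encodes an insulin-like growth factor binding protein, fell by 2.42 ± 0.13 on the log2 scale (adjusted p = 0.00121), from 27.4 to 5.79 CPM in D1 and from 13.2 to 2.06 CPM in D2 cells. Oprk1, the kappa opioid receptor gene, fell by 0.97 ± 0.06, from 73.0 to 37.7 CPM in D1 and 55.2 to 27.7 CPM in D2 cells. Nefm, a neurofilament subunit gene, fell by 0.88 ± 0.05, from 204.6 to 106.7 and from 166.7 to 94.0 CPM. Actn2, an actinin gene, fell by 0.96 ± 0.08, from 316.6 to 143.5 and from 281.2 to 164.2 CPM. Igfbp4 (ENSMUSG00000017493) lies on chromosome 11 at 99041244 to 99054392, Oprk1 (ENSMUSG00000025905) on chromosome 1 at 5588466 to 5606131, and Nefm (ENSMUSG00000022054) on chromosome 14 at 68082590 to 68124846 (GRCm38). The cannabinoid receptor gene Cnr1 fell by 0.42 ± 0.05 (adjusted p = 0.0274).

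In total 38 genes were lower and 21 higher in BACHD (edgeR adjusted p under 0.05, n = 2 pools each), 22 of them by a log2 change of at least 1 in size. Other genes that fell were Phex (-1.14 ± 0.10), Epyc (-0.88 ± 0.11), Peg10 (-0.76 ± 0.10), Galnt13 (-0.70 ± 0.06), the kinase gene Lrrk2 (-0.64 ± 0.05) and Cdr1 (-0.59 ± 0.06). At lower expression, Pkp2, a desmosomal plakophilin gene, fell by 2.73 ± 0.24, Bmp2 by 1.72 ± 0.17 and the neuropeptide gene Nts by 1.68 ± 0.15. Genes that rose included Olfm2 (0.83 ± 0.09), Vcan, which encodes versican and was listed as an oligodendrocyte precursor marker (0.45 ± 0.06), Adcyap1r1, the PACAP receptor gene (0.42 ± 0.05), mt-Nd4l (0.44 ± 0.05) and mt-Tl1 (0.59 ± 0.07). Slc17a7, a vesicular glutamate transporter gene, rose by 2.07 ± 0.23, but its D2 values were 0.668 and 0.864 CPM. Of the 21 genes that rose, 7 had a mean under 1 CPM in D2 cells. The counting interval excluded a ratio of 1 in each cell type for 38 of the genes that fell and 17 of those that rose, a count chosen after seeing the data.

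These 59 calls depend on the fit: edgeR called 0 genes without the expression filter (1595 at unadjusted p under 0.05), and 0 with genotype as the only term (382), and limma-trend on FPKM plus 0.1 called 0 (1712). DESeq2 called 77, of which 45 were shared, and total-count scaling in edgeR gave 144.

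**Figure D1:**
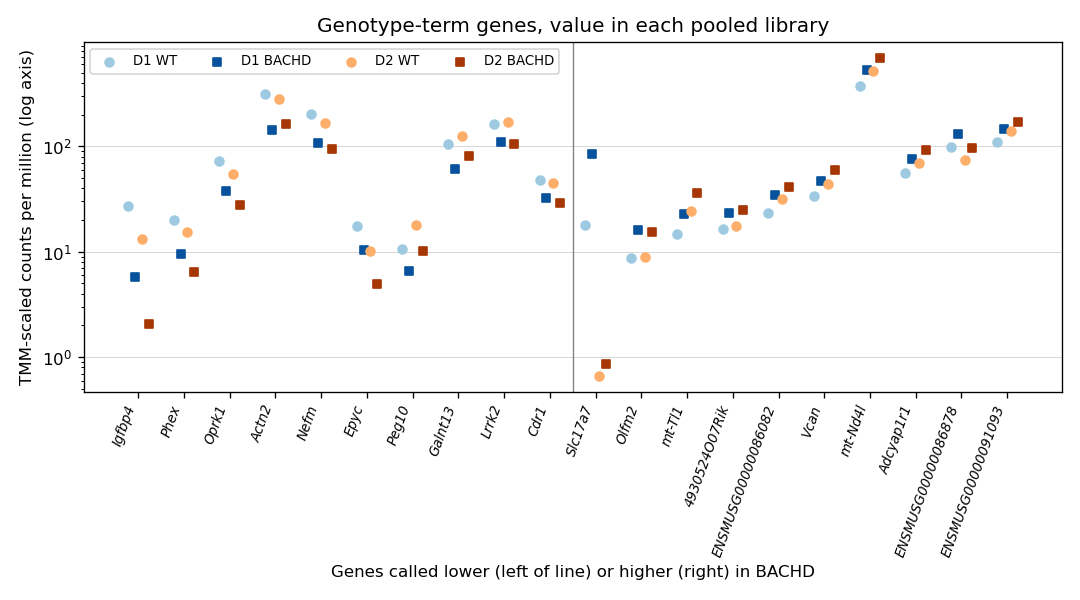
TMM-scaled CPM (log axis) in each of the 4 pooled libraries for the named genes called lower or higher in BACHD by the genotype term. Points are single libraries with no error bars; Igfbp4 went from 27.4 to 5.79 CPM in D1 and from 13.2 to 2.06 CPM in D2 cells, and Slc17a7 was under 1 CPM in both D2 libraries.

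Within D1 cells, the 6 measured markers of cortical glutamatergic neurons stood higher in the BACHD library. The 11 measured cortical genes of a separate test, described below, had a median log2 ratio of 0.02 (5 lower, 3 with a counting interval above 0). Slc17a7 was at 18.0 CPM in WT and 85.3 CPM in BACHD (log2 ratio 2.25, 95% counting interval 2.13 to 2.36). Neurod6 (2.38), Nrn1 (2.41), Tbr1 (2.10) and Hs3st2 (2.79) were also higher. Lower in D1 BACHD were Pkp2 (-3.11), Igfbp4 (-2.24), Bmp2 (-1.94), Odf4 (-1.27) and Cftr (-1.20). The size rule took 137 higher and 38 lower genes, of which 14 higher and 3 lower had a mean of at least 10 CPM. Of the 137, 72 were also called higher in D1 than D2 cells by the cell type term, to which a higher D1 BACHD value itself contributes.

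Within D2 cells, Serpina9 stood at 16.9 CPM in WT and 0.047 CPM in BACHD, that is 734 and 2 counts (log2 ratio -7.92, interval -11.55 to -6.64), and at 64.7 and 67.9 CPM in D1 cells. Igfbp4 (-2.68), Nts (-1.71), Phex (-1.25), Egr2 (-1.05), Fos (-1.05) and Epyc (-1.03) were lower in BACHD. The chemokine gene Cxcl14 was higher, at 13.7 and 30.6 CPM (1.16). The size rule took 37 higher and 42 lower genes in D2 cells, a balance that turned to 186 higher and 154 lower at a ratio of 1.5 and to 246 and 188 without the filter, and was 2 and 8 with a filter of 10 CPM. These comparisons are of single libraries and have no replicate check.

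Between the cell types, 7 genes passed as higher in both, where independent lists would share 0.378, and 12 as lower in both, where they would share 0.119. These expected numbers pool all genes tested, most of the genes that passed being weakly expressed. The shared genes were 0 higher and 2 lower with a filter of 10 CPM, 3 and 9 with FPKM plus 0.1, and 39 and 33 at a ratio of 1.5. Another 4 passed in opposite directions, named here after their values were seen: Grm2 (1.10 in D1 and -1.12 in D2 cells), Ccn1 (counting intervals 1.82 to 3.24 and -2.51 to -1.12), Rsph3b (1.14 and -1.45) and ENSMUSG00000073883 (-1.36 and 2.86). Across all 13400 genes, the log2 ratios of D1 and D2 cells had a Pearson correlation of 0.249 and a Spearman correlation of 0.279. Genes are not independent replicates, and the comparisons share no library.

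**Figure D2:**
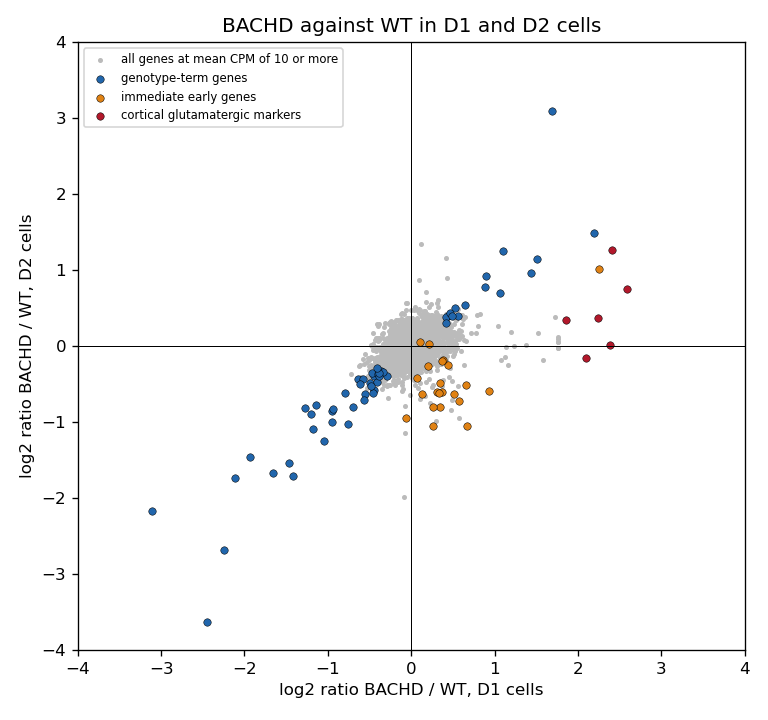
Log2 ratio of BACHD to WT in D1 cells (x axis) and D2 cells (y axis), where grey points are the 9477 genes with a mean of at least 10 CPM, 1 of which lies outside the axes, and coloured points are genotype-term genes, immediate early genes and cortical glutamatergic markers at any expression. The immediate early genes have a median of 0.34 in D1 and -0.59 in D2 cells.

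Of 33 medium spiny neuron genes shared by both pathways and listed for lower expression in Huntington's disease striatum, 24 were lower in D1 and 25 in D2 cells, with median log2 ratios of -0.07 (percentile 11.5 of random lists) and -0.08 (percentile 0.08). In the same comparisons, markers of oligodendrocytes had medians of 0.34 and 0.40, of astrocytes 0.41 and 0.12, of microglia 0.17 and 0.25 and of cortical glutamatergic neurons 2.31 and 0.36. Actn2 and Cnr1 fell, and adjusted over the list alone 7 fell. Pde10a, a striatal phosphodiesterase gene, was at 2095 and 1634 CPM in D1 and 2322 and 1860 CPM in D2 cells (-0.34 ± 0.06, adjusted p = 0.0700). Ppp1r1b, which encodes DARPP-32, was at -0.13 ± 0.07 and Drd2 at -0.02 ± 0.06, with adjusted p of 0.433 and 0.909. The list was lower by camera (adjusted p = 0.00438, and adjusted p = 0.663 with an estimated correlation). Direct-pathway markers had medians of -0.07 in D1 (percentile 11.0) and -0.39 in D2 cells (percentile 0), where they are scarce, and indirect-pathway markers -0.06 (percentile 16.6) and -0.06 (percentile 9.9).

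Immediate early genes, which respond to neuronal activity, stood higher in D1 BACHD than D1 WT for 21 of 22 genes (median log2 ratio 0.34) and lower in D2 BACHD than D2 WT for 19 of 22 (median -0.59). Fos stood at 30.9 and 49.0 CPM in D1 cells and at 85.6 and 41.3 CPM in D2 cells (WT, then BACHD). Arc stood at 304.4, 451.8, 760.7 and 460.8 CPM, and Nr4a1 at 236.3, 283.0, 467.8 and 268.8 CPM (D1 WT, D1 BACHD, D2 WT, D2 BACHD). Over both cell types the list did not pass (camera adjusted p = 0.640), and Nr4a2 was its called member (2.12 on the log2 scale, with 1.36 and 6.46 CPM in D1 and 0.092 and 0.187 CPM in D2 cells). The cortical glutamatergic markers had a median of 2.31 in the same D1 comparison and 0.36 in D2 cells. Heat shock chaperone genes had medians of -0.04 in D1 and -0.15 in D2 cells.

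Mitochondrially encoded genes rose as a group (camera adjusted p = 2.54e-10, and adjusted p = 0.663 with an estimated correlation). All 25 measured were higher in D1 BACHD and 23 in D2 BACHD, with medians of 0.47 and 0.15, and 17 rose adjusted over the list alone. The D1 WT library had the lowest mitochondrial share of the 4. Nuclear genes of oxidative phosphorylation were lower (65 of 77 in D1 and 47 in D2 cells, medians -0.11 and -0.03, camera adjusted p = 0.000118, and 0.690 as adjusted p with an estimated correlation). Sdha was at -0.28 ± 0.05 and Atp5a1 at -0.24 ± 0.05, and no member was called. Proteasome subunit genes had medians of -0.11 and -0.03 (camera adjusted p = 0.00438, and adjusted p = 0.663 with an estimated correlation).

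Oligodendrocyte markers rose (8 of 9 higher in D1 and 9 in D2 cells, medians 0.34 and 0.40, camera adjusted p = 7.19e-07, and adjusted p = 0.663 with an estimated correlation), with Mobp at 0.33 ± 0.06. Astrocyte markers had medians of 0.41 and 0.12 (adjusted p = 0.0129) and microglia markers 0.17 and 0.25 (adjusted p = 0.0418), each with an adjusted p of 0.663 with an estimated correlation. Cortical glutamatergic markers rose (6 of 6 higher in D1 and 4 in D2 cells, where Tbr1 had 18 and 16 counts and Neurod6 2 and 1, medians 2.31 and 0.36, adjusted p = 0.00312, and adjusted p = 0.663 with an estimated correlation), and their summed CPM in D1 cells was 28.4 in WT and 134.5 in BACHD. Adjusted over the list alone, 7 oligodendrocyte and 6 cortical markers rose. Genes of cAMP and dopamine signalling (medians -0.05 and -0.06; 2 fell adjusted over the list alone) and striatal matrix genes (-0.17 and -0.13; 3 fell adjusted over the list alone) were also lower by camera, each with an adjusted p of 0.0418, or 0.663 with an estimated correlation. In all, 10 of 31 lists passed by camera and none with an estimated correlation. With 1 residual degree of freedom the second test could hardly pass a list, and the first does not measure spread between pools. Neither result decides whether a list would change in other pools.

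**Figure D3:**
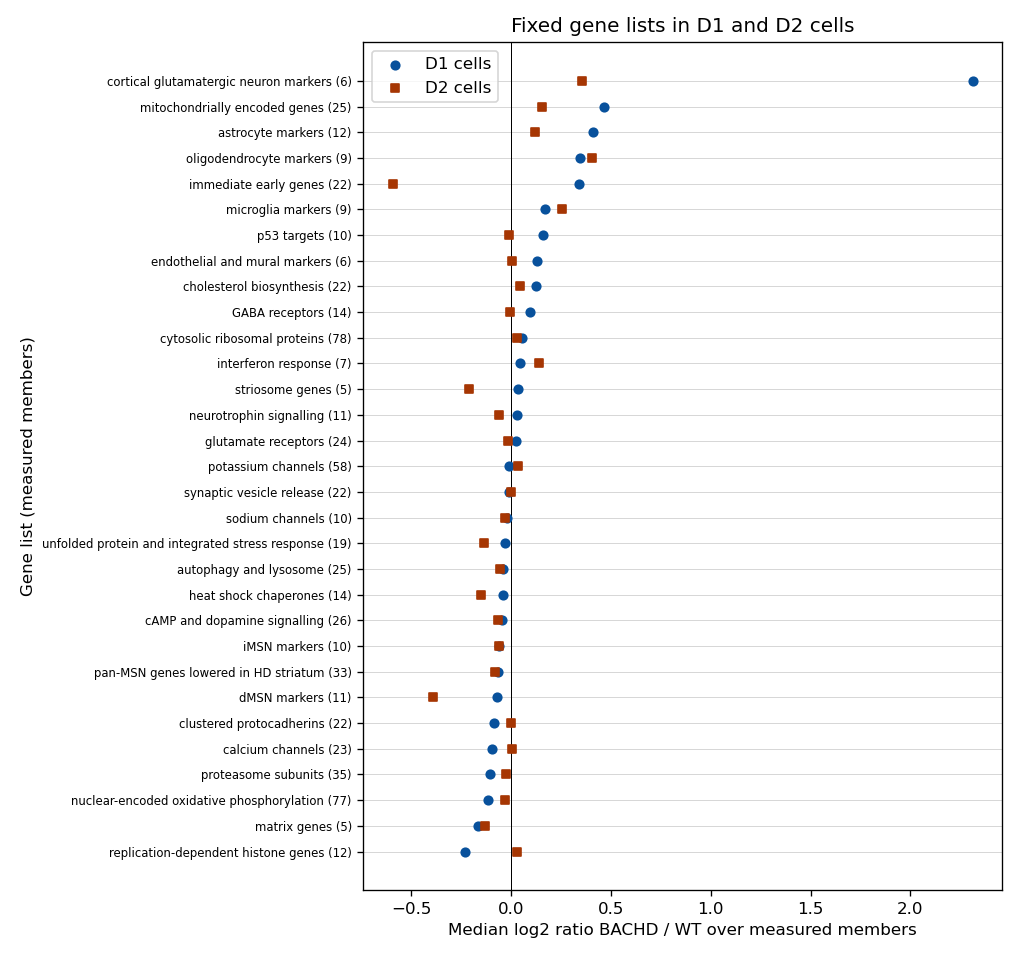
Median log2 ratio of BACHD to WT over the measured members (number in brackets) of each of 31 gene lists, in D1 cells (circles) and D2 cells (squares). Cortical glutamatergic markers lie at 2.31 in D1 cells, and immediate early genes lie at 0.34 in D1 and -0.59 in D2 cells.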

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

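The test of further cortical genes was set before its result was seen, and the other tests in this part were chosen after the results they bear on. With 1 library per group, none of the differences between cell types given here was tested.

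Immediate early genes pointed opposite ways in the cell types. Their median log2 ratio of BACHD to WT was 0.34 in D1 cells (21 of 22 higher) and -0.59 in D2 cells (19 of 22 lower), a difference of -0.94. The summed CPM of the list was 2254 in D1 WT and 3715 in D2 WT, and 2746 in D1 BACHD and 2577 in D2 BACHD. By these sums the BACHD pools were closer to each other than the WT pools. The opposite signs rest on single pools, and these sums cannot tell which of the pools carry them. Counting noise was argued against, since 16 of the 22 were higher in D1 and lower in D2 cells with both counting intervals excluding a ratio of 1. A general stress difference between pools from handling stays open: heat shock chaperones had a median of -0.149 in D2 and -0.04 in D1 cells, and each group is 1 pool, so handling and genotype cannot be told apart. A genotype effect that depends on cell type is also open and untested, as is any share in the D1 values of the cells behind the cortical glutamatergic markers (median 2.31 in D1).

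Counting intervals excluded a ratio of 1 in opposite directions for 16 tested genes that passed the size rule in a cell type. The 5 of them taken by the naming rule were Fos (D2 minus D1 log2 ratio -1.72), Egr2 (-1.32), Cck (-2.49), Ahcy (1.45) and Gnas (-1.27). Gnas overlaps Gm20721 on chromosome 2, so the split of reads between them is uncertain.

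Cortical glutamatergic markers were higher in the D1 BACHD library by 1.86 to 2.59 (log2) in all 6 measured. A lower share of medium spiny neurons with every other cell type raised alike was argued against, since the cortical median exceeded the highest glial or vascular median by 1.90. Cortical neurons left by the GFP sort may be the source (Slc17a7 stood at 85.3 CPM in D1 BACHD), but 11 measured cortical genes outside the list had a median of 0.0209 (5 lower, 3 with a counting interval above 0), which met the bound set beforehand against this explanation. That bound was judged wrong only after the result was seen, because 10 of the 11 stood at 5 CPM or more in D2 cells. A high level could hide a small share, as for Syt6 (463.2 CPM in D2 WT). Slc30a3, the exception, was at 1.99 and 8.14 CPM in D1 WT and D1 BACHD. Cux2 (7.66 and 7.52 CPM), Etv1 (6.65 and 7.81) and Bcl6 (10.9 and 11.7) stood below Slc17a7 in D1 WT (18.0). Their D1 counting intervals included a ratio of 1. In D2 WT and D2 BACHD, however, Cux2 stood at 7.65 and 8.29 CPM, Etv1 at 7.49 and 5.00 and Bcl6 at 16.8 and 13.4. Slc17a7 was at 0.668 and 0.864 CPM there. Such a level in the sorted neurons could hide a small share, so Cux2, Etv1 and Bcl6 decide neither way. The 11 genes go both ways, so the test does not settle the source. The summed CPM of the 6 markers was 28.35 in D1 WT and 134.5 in D1 BACHD, against 1.498 in D2 WT and 2.055 in D2 BACHD. The markers thus stood higher in the D1 than the D2 sort without the transgene, though these sorts also differ in reporter line. That gap leaves the source of the further rise in D1 BACHD open. For that rise, cortical cells and a genotype effect in D1 neurons cannot be told apart from 1 pool per group.

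Genes beside Drd2 were higher in D2 libraries: 3 of 4 tested genes within 250 kb (Tmprss5, Ankk1 and Ttc12, but not Ncam1) were called higher in D2 cells, against 6.69% of other genes. Ttc12 and Ankk1 had prompted the question, and Ttc12 is also on the indirect-pathway marker list. Without these genes 1 of 2 was called (one-sided Fisher's exact test, p = 0.130), too few to decide. Sfxn1 and Hrh2, tested within 250 kb of Drd1, were called higher in D1 cells. Their D2 minus D1 log2 differences were -4.41 (edgeR adjusted p = 7.26e-09) and -1.385 (adjusted p = 0.00365). Sfxn1 is also on the direct-pathway marker list. For either receptor gene, passenger genes of the reporter line and genes regulated with the receptor gene cannot be told apart, since the design confounds cell type with line.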

How the results depend on the processing

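The genotype count limited to genes whose counting intervals excluded a ratio of 1 in each cell type (55), the D1 count without genes called higher in D1 than D2 cells and the crosswise grouping were chosen after the results were seen. No single gene or list value that had passed changed sign under the alternatives run, but the balance of higher and lower genes in D2 cells turned from 37 and 42 to 186 and 154 at a ratio of 1.5 and to 246 and 188 with no filter, and that of shared genes from 7 and 12 to 39 and 33 at a ratio of 1.5. Among values for single genes and lists, 1155 comparisons gave the same side of the threshold or lay within the counting interval, 31 were weaker, 25 stronger and 60 moved. Filters change which genes are tested, and ratio and adjusted p limits change what passes; for the other settings the cause was not tested.

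Against 175 genes in D1, 79 in D2 and 19 shared under the size rule, no filter gave 670, 434 and 50, a filter of 10 CPM gave 19, 10 and 2, a ratio of 1.5 gave 497, 340 and 72, FPKM plus 1 gave 50, 13 and 3, and FPKM plus 0.1 with no filter gave 1277, 1011 and 140. With FPKM plus 0.1 the shared count was 12. Without genes called higher in D1 than D2 cells, 93 remained in D1, which says little, since a gene higher in D1 BACHD is thereby more readily called higher in D1 cells. Total counts gave 172, 79 and 19, and DESeq2 size factors gave 175, 79 and 19.

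Against 59 genotype calls, total counts gave 144, an adjusted p under 0.1 gave 142, no filter 0, only the term tested 0, limma-trend 0 on FPKM plus 0.1 and 1 on FPKM plus 1. With 3 libraries both terms leave no residual degree of freedom, so leaving out each library in turn was run with only the term tested, which gave 0 to 0 and does not show what a left-out library does to the 59. At an unadjusted p under 0.05 there were 138 genes without D1 WT, 174 without D1 BACHD, 245 without D2 WT and 210 without D2 BACHD in edgeR, 1595 with no filter, 382 with only the term tested and 1712 with limma-trend on FPKM plus 0.1. Where a library was left out, a group with 1 library is assumed to vary like the other. DESeq2 called 77 and DESeq2 size factors in edgeR 88. With the libraries grouped crosswise (D1 WT and D2 BACHD against the others), edgeR called 0 genes, with 201 at unadjusted p under 0.05 against 1801 for genotype, but the residual of that fit holds the genotype effect.

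Against 2274 cell type calls, DESeq2 gave 1330, no filter 810, and only the term tested 1449. Against that 1449, leaving out each library in turn gave 821 (without D2 WT) to 1400 (without D1 WT), with 887 without D2 BACHD and 1364 without D1 BACHD. With an estimated correlation, 0 lists passed camera against 10, which says little, since that test has 1 residual degree of freedom. Libraries held 41325647 to 44523622 counts, and a count of 3 was 0.0674 to 0.0726 CPM, so depth limits ratios of genes near that level, such as Neurod6 in D2 cells (2 and 1 counts).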

Other observations

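The list tests in this part were planned. Of the 31 lists, 15 in D1 and 13 in D2 cells lay outside the central 95% of random lists. Random lists hold unrelated genes, so a list whose members move together in a single library lies outside more readily. The percentiles describe these libraries and are not tests. Several lists not described above stood apart in 1 cell type only by their place among random lists, without a test of the difference. In D1 cells, cholesterol synthesis genes had a median log2 ratio of 0.12 (percentile 99.7), GABA receptor genes 0.10 (percentile 99.8) and p53 target genes 0.16 (percentile 99.6). Replication-dependent histone genes (-0.23, percentile 0.11), calcium channel genes (-0.10, percentile 0.77) and clustered protocadherins (-0.09, percentile 1.67) lay low in D1 cells. In D2 cells, unfolded protein response genes had a median of -0.14 (percentile 0.01), striosome genes -0.21 (percentile 0.07) and autophagy and lysosome genes -0.06 (percentile 1.53). Cytosolic ribosomal protein genes lay high in both, with medians of 0.05 (percentile 100) and 0.03 (percentile 98.8). Hspa5, the BiP chaperone gene, was at 253.5 and 181.2 CPM in D2 WT and D2 BACHD. Camera on the genotype term had an adjusted p of 0.0763 for cholesterol synthesis, 0.126 for p53 targets, 0.254 for histones, 0.126 for calcium channels, 0.206 for the unfolded protein response and 0.277 for striosome genes.

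The other lists gave camera adjusted p of 0.0687 for heat shock chaperones, 0.0687 for cytosolic ribosomal proteins, 0.0581 for clustered protocadherins, 0.0801 for direct-pathway markers, 0.254 for indirect-pathway markers, 0.640 for immediate early genes, 0.640 for glutamate receptors, 0.360 for GABA receptors, 0.959 for potassium channels, 0.254 for sodium channels, 0.193 for neurotrophin signalling, 0.155 for autophagy and lysosome, 0.126 for interferon response, 0.544 for synaptic vesicle release and 0.470 for endothelial and mural markers. Adjusted over the list alone, 2 direct-pathway and 2 indirect-pathway markers fell, as did 2 neurotrophin, 1 unfolded protein response, 1 striosome and 1 synaptic vesicle gene. By the same adjustment 5 potassium channel genes rose and 3 fell, 1 calcium channel gene rose and 3 fell, 1 GABA receptor gene rose and 1 fell, and 1 immediate early gene rose. Too few genes were measured to test developmental transcription factors (2), oligodendrocyte precursors (2), cholinergic interneurons (1), GABA interneurons (4), ependymal cells (1) and blood cells (0).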
